A study of Homo sapiens with 18 samples.

How the data were processed

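The series measured polyadenylated RNA in HAP1 cells, a near-haploid human line derived from the chronic myeloid leukaemia line KBM-7. Per the labels, 3 cell lines were used: the parental line (WT), a line carrying an ATG7 knockout (ATG7KO) and a line carrying an RB1CC1 knockout (RB1CC1KO). ATG7 is the E1-like enzyme that activates ATG12 and the ATG8 proteins during autophagosome formation. RB1CC1, also called FIP200, is a scaffold of the ULK1 complex that starts autophagy. Cells were grown in full medium with 10% serum or placed for 6 h in Earle's balanced salt solution (EBSS), which holds glucose and salts but no amino acids or serum. Each of the 6 groups had 3 libraries, and the labels state that RNA came from independent biological replicates. Groups and replicate numbers were taken from the sample labels alone.

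Per the labels' protocols, libraries were made from bead-selected polyadenylated RNA with a directional kit and sequenced as 75 bp single-end reads. The values are counts: the authors deposited 1 table of whole-number read counts per gene for each library, with 63677 Ensembl gene identifiers and 5 summary lines, and no normalization. The submitters' processing notes name STAR 2.4.2a, Picard, HTSeq 0.6.1p1, edgeR, DESeq2 and the genome build GRCh37 (hg19), without saying what each was used for. The strand setting of the counting, the annotation release and any read filter are not given in the sources used here. Reads of overlapping genes on opposite strands can therefore not be told apart with certainty, and reads of near-identical copies may have been lost or shared. The 5 summary lines were left out of library sizes and tests. Reads that fell in no gene made up between 9.39% and 15.1% of the uniquely aligned reads, and reads that fell in more than 1 gene between 2.08% and 2.42%.

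Gene names, gene types, exon numbers and chromosomes were taken from the GENCODE 29 annotation of GRCh38, which matched 52526 of the 63677 identifiers. This annotation belongs to another build than the one the notes name. It was used for names and for which chromosome holds a gene, and coordinates are printed for the knockout targets only, as GRCh38 positions.

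Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes with enough reads for testing in the 6 groups (edgeR's filterByExpr) were kept, which left 15179. Library sizes were scaled with the TMM method, and 1 quasi-likelihood model with a mean for each of the 6 groups was fitted to all 18 libraries with robust estimation of the spread. The common biological coefficient of variation was 6.72%. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 in edgeR's quasi-likelihood F test, and all adjusted p-values of genes come from that test. The 10 comparisons were EBSS against full medium in each line, each knockout-labelled line against WT in each medium, the 2 knockout-labelled lines in full medium, and the difference of the EBSS response between each knockout-labelled line and WT. Log2 fold changes are given with a standard error derived from the test, the size of the change divided by the square root of its F statistic. It is not the standard error of a fitted coefficient. The values of 2 responses therefore need not combine to that of their difference. Expression levels are given as TMM-scaled CPM with the SD over libraries.

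The comparisons, the tests, the rule for naming genes, the alternatives and 27 gene lists were chosen before the data were examined. The lists cover nutrient and stress responses, growth, the cell cycle, metabolism and markers of other cell types. Of 698 list entries 696 were matched, and ACACA and UHRF1 had no match. Besides ATG7 and RB1CC1, the rule took protein-coding genes with the largest log2 fold changes among those called, with a mean log2 CPM of at least 1 and, for comparisons of 2 groups, with no overlap between the groups' libraries. It took 8 genes in each direction for EBSS in WT and for each knockout-labelled line against WT in full medium, and 4 otherwise. From each list described it took up to 4 members with the smallest p. Lists were compared with all other genes by camera with a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. The adjusted p of a list is from this test unless it is given with an estimated correlation. Where a group had no reads of a gene, a bound was computed with 3 counts over the group, and with 1 to 3 reads the ratio is given with its 95% counting interval. These bounds and intervals cover counting error only.

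Depth ranged from 4892072 to 26005942 reads in genes per library. The model was tested on simulated counts drawn from the libraries' means and sizes, with 200 of 15179 genes changed. At a 2-fold change it recovered 79.1% of the changed genes for EBSS in WT, 85.1% for ATG7KO against WT in full medium, 86.6% for RB1CC1KO against WT in full medium and 76.1% for the difference of responses between ATG7KO and WT. At 1.5-fold the shares were 65.7%, 67.2%, 67.2% and 47.8%. Unchanged genes made up 6, 16, 11 and 9 of the calls, or 3.64%, 8.79%, 6.21% and 5.96%, beside the nominal 5%, in 1 simulation each. The data held many more called genes than the 200 simulated: 9788 for EBSS in WT, and 1599 and 2606 for the knockout-labelled lines against WT in full medium. The threshold for a call and the scaling depend on that number, so the simulated shares do not carry over to those comparisons.

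The alternatives were DESeq2 size factors and upper-quartile scaling in the same model, DESeq2 1.42.0, no filter, a stricter filter, a fit of the compared groups alone, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were the percent of reads in no gene as a covariate, and leaving out the shallowest library in comparisons that do not contain it. Figures and tests of single explanations were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Overlaps of calls against shared WT libraries were set beside 20 simulations of unchanged groups, in which the WT libraries were simulated too.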

Results

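The data consisted of 18 RNA-seq libraries of HAP1 cells, 3 for each combination of 3 cell lines with full medium or 6 h of EBSS. Reads in genes per library ranged from 11994110 to 19073798 in 16 libraries. ATG7KO EBSS replicate 3 had 4892072 and RB1CC1KO EBSS replicate 2 had 26005942. The shallow library detected 17418 genes, against 19611 to 22065 in the others. Reads of the mitochondrial genome took 3.24 to 4.26% of the reads in full medium and 1.41 to 2.36% after EBSS, so that this share was lower in all 9 starved libraries than in all 9 fed ones. Replicate pairs differed by more than sampling noise, with chi-square values per degree of freedom from 2.33 to 11.2, and no library was a repeat of another. The first principal component of the 2000 most variable genes held 61.0% of the variance, the second 16.8% and the third 10.6%.

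The targeted genes were examined first. ATG7 (ENSG00000197548, chromosome 3, 11272309 to 11557665, plus strand, GRCh38) stood at 15.6 ± 1.30 CPM (SD, n = 3) in WT in full medium and at 4.02 ± 0.436 CPM in ATG7KO. This is a log2 fold change of -1.95 ± 0.12 (adjusted p = 8.81e-15). After EBSS the level was 16.1 ± 1.68 CPM in WT and 10.4 ± 0.53 CPM in ATG7KO (log2 fold change -0.62 ± 0.12, adjusted p = 0.000149). RB1CC1 (ENSG00000023287, chromosome 8, 52622456 to 52745843, minus strand, GRCh38) was not reduced in the libraries labelled RB1CC1KO. It stood at 105 ± 10.3 CPM in WT and 157 ± 12.7 CPM in RB1CC1KO in full medium (log2 fold change 0.58 ± 0.07, adjusted p = 8.3e-08). After EBSS it stood at 222 ± 10.8 and 264 ± 14.8 CPM (0.25 ± 0.07, adjusted p = 0.00472). Whole-gene counts do not show a small coding change, and the edited positions are not given in the sources used here. The RNA level therefore gives no check of the RB1CC1KO label, and these libraries are called RB1CC1KO-labelled from here on.

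**Figure D1:**
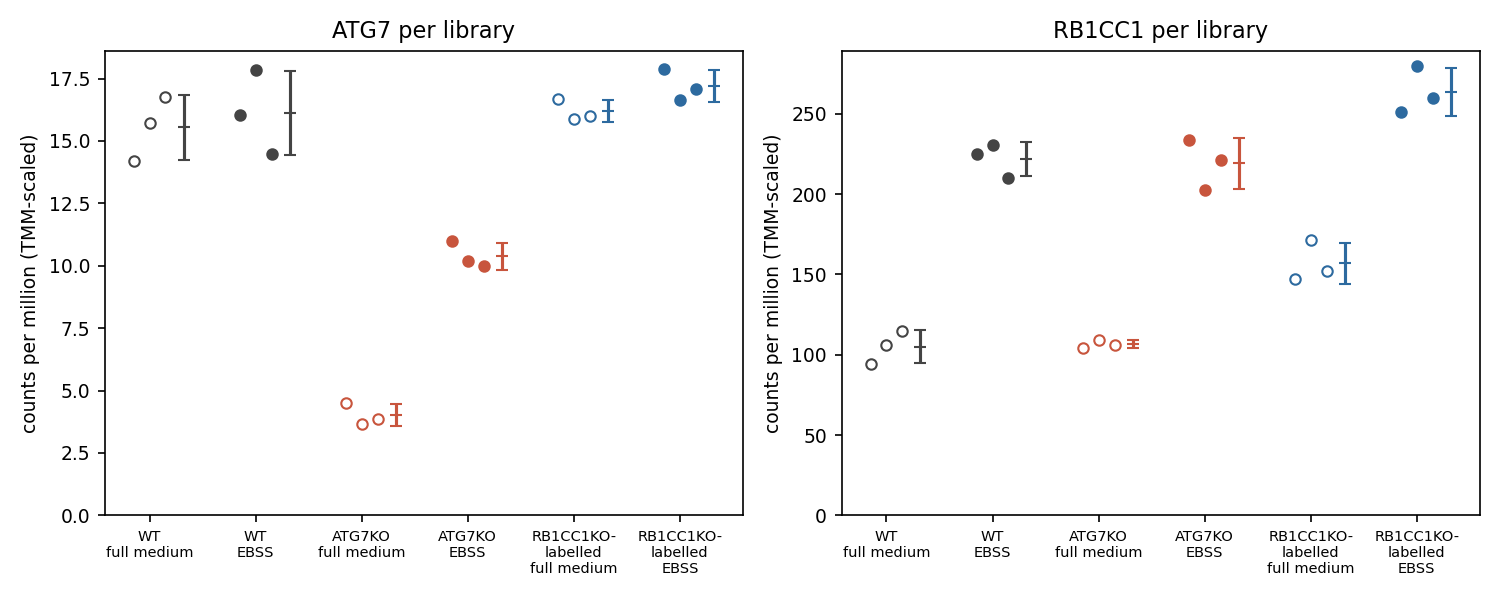
TMM-scaled CPM of ATG7 (left) and RB1CC1 (right) in each library, 3 per group, open circles for full medium and filled circles for EBSS, with the group mean and SD at the right of each group. ATG7 is at 4.02 CPM in ATG7KO in full medium and 10.4 CPM after EBSS, and RB1CC1 is higher in the RB1CC1KO-labelled libraries than in WT in both media.

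The first comparison asked how WT cells respond to 6 h of EBSS in place of full medium. EGR1 rose from 7.77 ± 1.54 to 1795 ± 169 CPM (SD, n = 3), a log2 fold change of 7.89 ± 0.11 (adjusted p = 5.84e-30), FOS by 6.77 ± 0.15 and EGR2 by 6.35 ± 0.19. DDIT4, an inhibitor of mTORC1, rose by 5.54 ± 0.10 and INHBE, a subunit of activin E, by 5.50 ± 0.22. MYH15 (5.31 ± 0.25) and AVIL (5.12 ± 0.28) completed the set with LTA, which had 1 read in full medium and 112 after EBSS, a ratio of 114 with an interval of 20.1 to 4546. The largest falls were in TTC30B (-4.83 ± 0.21), the arrestin-like ARRDC3 (-4.09 ± 0.12), TMEM177 (-4.02 ± 0.18), the transporter SLC16A6 (-3.76 ± 0.21), CCDC71 (-3.73 ± 0.15), ZNF287 (-3.67 ± 0.27), WDR5B (-3.61 ± 0.21) and PLPP6 (-3.61 ± 0.18). TTC30B, WDR5B and PLPP6 have 1 exon, and TTC30B has a close paralogue. Of 15179 genes, 9788 were called, 4923 higher and 4865 lower, and 2987 of them changed at least 2-fold. Upper-quartile scaling put the median gene at -0.17 in place of -0.02 and the share of higher calls at 37.4% in place of 50.3%, so directions of small changes are relative to the scaling.

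The amino acid response rose as a group in WT. Of 31 measured genes of the ATF4 programme, which is switched on when uncharged tRNA accumulates, 30 rose and 1 was not called (adjusted p = 9.3e-102). Adjusted over the list alone, 30 rose and 1 fell. The 4 leading members were STC2 (3.50 ± 0.06), DDIT4, DDIT3 (4.23 ± 0.08) and the glutamine carrier SLC38A2 (3.54 ± 0.08). Of 12 serine and one-carbon enzymes 8 rose and 2 fell (adjusted p = 7.38e-08), with PSAT1 at 2.21 ± 0.06, MTHFD2 at 1.96 ± 0.06 and PHGDH at 1.38 ± 0.06. Of 21 cytosolic aminoacyl-tRNA synthetase genes 13 rose and 4 fell (adjusted p = 2.36e-08), with CARS1 at 2.10 ± 0.06 and TARS1 at 1.74 ± 0.06. The counts of the last 2 lists were the same when adjusted over the list alone. All 3 lists also passed with an estimated correlation (adjusted p = 1.35e-06, 0.00613 and 0.03).

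Genes of autophagy and the lysosome rose as well. Of 30 measured genes of the autophagy machinery, a list without ATG7 and RB1CC1, 22 rose, 3 fell and 5 were not called (adjusted p = 0.000432). MAP1LC3B, which encodes an ATG8 protein of the autophagosome membrane, rose by 1.31 ± 0.06, UVRAG by 1.59 ± 0.08, GABARAP by 2.76 ± 0.20 and WIPI2 by 0.81 ± 0.06. MAP1LC3B has a near-identical copy in the genome, so its reads may not be its own alone. GABARAP had few reads, 54 in full medium (1.15 ± 0.243 CPM) and 360 after EBSS (7.87 ± 0.674 CPM). Of 14 autophagy receptors 10 rose and 0 fell (adjusted p = 3.3e-05), with CALCOCO2 at 1.53 ± 0.07, SQSTM1 at 0.93 ± 0.06, TAX1BP1 at 1.02 ± 0.07 and OPTN at 1.12 ± 0.08. Of 43 lysosomal genes 26 rose and 5 fell (adjusted p = 3.3e-05). The leading members were the regulators FLCN (2.86 ± 0.08), RRAGC (2.12 ± 0.07), FNIP1 (2.05 ± 0.07) and FNIP2 (1.58 ± 0.07), which control mTORC1 at the lysosome and are not hydrolases. The counts adjusted over the list alone were the same, and with an estimated correlation the lists passed at adjusted p = 0.0163, 0.0154 and 0.0154. With upper-quartile scaling their medians stayed above 0, at 0.32, 0.60 and 0.15.

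Immediate early and ERK feedback genes formed the other large group, with 24 of 26 higher and 1 lower in WT (adjusted p = 3.41e-39, 0.000288 with an estimated correlation). ATF3, which is also a member of the ATF4 list, rose by 4.09 ± 0.09 and KLF6 by 2.83 ± 0.06, besides EGR1 and EGR2. Of 22 FOXO targets, genes derepressed when insulin signalling stops, 16 rose and 4 fell (adjusted p = 5.45e-09, 0.00116 with an estimated correlation), led by TSC22D3 (4.22 ± 0.08), CCNG2 (2.81 ± 0.07), BCL6 (2.20 ± 0.10) and CDKN1B (1.22 ± 0.06). Of 33 ribosome biogenesis genes 21 fell and 3 rose (adjusted p = 6.12e-05, 0.035 with an estimated correlation), among them GRWD1 (-1.35 ± 0.08), RRS1 (-1.36 ± 0.09), MYBBP1A (-1.12 ± 0.07) and NIP7 (-0.97 ± 0.07). All 3 counts were the same when adjusted over the list alone. RRS1 has 1 exon.

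Other groups moved less clearly in WT. Of 25 genes of cholesterol synthesis and uptake 15 fell and 5 rose (adjusted p = 0.0213), with MSMO1 at -1.56 ± 0.10, but adjusted p = 0.163 with an estimated correlation. Of 30 G2/M genes 22 rose and 3 fell (adjusted p = 4.27e-05, but adjusted p = 0.177 with an estimated correlation), with AURKA at 1.02 ± 0.06 and TTK at 1.31 ± 0.07. Of 23 genes of the unfolded protein response 11 rose and 7 fell (adjusted p = 0.00812, but adjusted p = 0.102 with an estimated correlation). Their median was 0.08 and turned to -0.08 with upper-quartile scaling. HERPUD1 (3.50 ± 0.06) and XBP1 (2.15 ± 0.06) led them. The counts of these lists were the same when adjusted over the list alone. Of 13 mitochondrially encoded mRNAs 5 fell and 0 rose, with MT-ND5 at -0.69 ± 0.20, and the list did not pass (adjusted p = 0.317). Adjusted over the list alone, edgeR called 0 of these 13, with 5 at an unadjusted p under 0.05 and 5 called by DESeq2 over all genes.

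**Figure D2:**
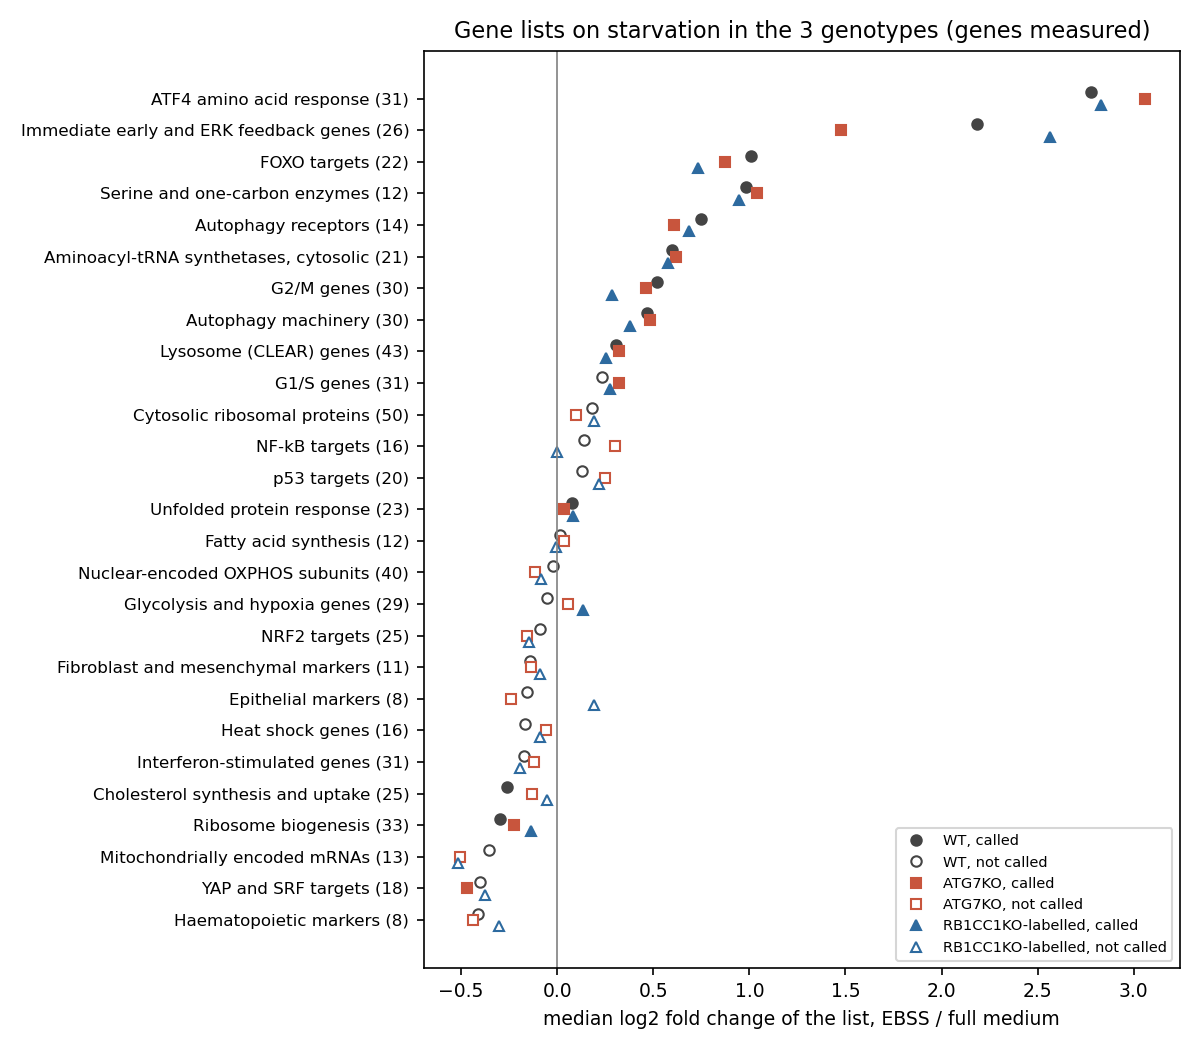
Median log2 fold change of each gene list between EBSS and full medium in WT (circles), ATG7KO (squares) and RB1CC1KO-labelled libraries (triangles), with filled symbols for lists at a camera adjusted p below 0.05 and the number of measured genes in brackets. The ATF4 list has medians of 2.78, 3.06 and 2.83 and ribosome biogenesis lies below 0 in each line.

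The same contrast in ATG7KO asked how the cells labelled ATG7KO respond. EGR1 rose by 6.95 ± 0.11, FOS by 6.88 ± 0.15 and EGR2 by 6.41 ± 0.22 (7.73 without ATG7KO full medium replicate 2), and LTA was at least 47.6-fold higher, with 95 reads after EBSS and 0 before. TMEM177 (-4.52 ± 0.22), SLC40A1 (-4.09 ± 0.42), TTC30B (-4.09 ± 0.23) and CCDC71 (-4.03 ± 0.17) fell most. ATG7 itself rose by 1.38 ± 0.14 (adjusted p = 5.37e-11) and did not pass in WT (0.05 ± 0.10, adjusted p = 0.683). Of the ATF4 genes 30 of 31 rose and 1 fell, of the autophagy machinery 19 of 30 rose and 2 fell, of the receptors 11 of 14 rose and 0 fell, and of the lysosomal genes 26 of 43 rose and 4 fell. MAP1LC3B rose by 1.20 ± 0.06, UVRAG by 1.77 ± 0.08 and ULK1 by 1.34 ± 0.09. Adjusted over the list alone, these counts were the same, and the lists passed with an estimated correlation (adjusted p = 1.36e-07, 0.0185, 0.0184 and 0.0112). Ribosome biogenesis genes fell in 19 of 33 cases and rose in 3, also adjusted over the list alone (adjusted p = 0.000415, but adjusted p = 0.0663 with an estimated correlation). In all, 9554 genes were called, 4902 higher and 4652 lower, with 2911 at least 2-fold, and upper-quartile scaling put the higher share at 37.2% in place of 51.3%.

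In the RB1CC1KO-labelled cells FOS rose by 8.78 ± 0.16, EGR1 by 8.77 ± 0.12 and EGR2 by 7.47 ± 0.20, and LTA went from 3 to 328 reads, a ratio of 102 with an interval of 34.7 to 499. TTC30B (-5.10 ± 0.20), TMEM177 (-4.61 ± 0.19), ZNF287 (-4.55 ± 0.29) and the mitochondrial synthetase gene PARS2 (-4.53 ± 0.19) fell most. RB1CC1 rose by 0.75 ± 0.07, after 1.08 ± 0.07 in WT and 1.04 ± 0.07 in ATG7KO. Of the ATF4 genes 30 of 31 rose and 1 fell, of the autophagy machinery 20 of 30 rose and 3 fell, of the receptors 11 of 14 rose and 0 fell, and of the lysosomal genes 23 of 43 rose and 7 fell. Adjusted over the list alone, the machinery had 20 higher and 4 lower and the other counts were the same. With an estimated correlation these lists passed (adjusted p = 6.51e-07, 0.035, 0.035 and 0.0443). In all, 9886 genes were called, 4835 higher and 5051 lower, with 3261 at least 2-fold, and upper-quartile scaling put the higher share at 37.0% in place of 48.9%.

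The 3 responses were close to one another and share no library. Across genes, which are not independent replicates, the correlation of log2 fold changes was 0.904 between WT and ATG7KO, 0.880 between WT and the RB1CC1KO-labelled line and 0.895 between the latter 2 lines. Between WT and ATG7KO 4177 genes were higher in both, 3842 lower in both and 26 opposite, against 1589.9, 1491 and 3079.9 from independent lists of these sizes. Between WT and the RB1CC1KO-labelled line the counts were 4108, 3955 and 65. In all 3 lines 3829 genes rose and 3541 fell, of which 1059 and 991 changed at least 2-fold in each.

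**Figure D3:**
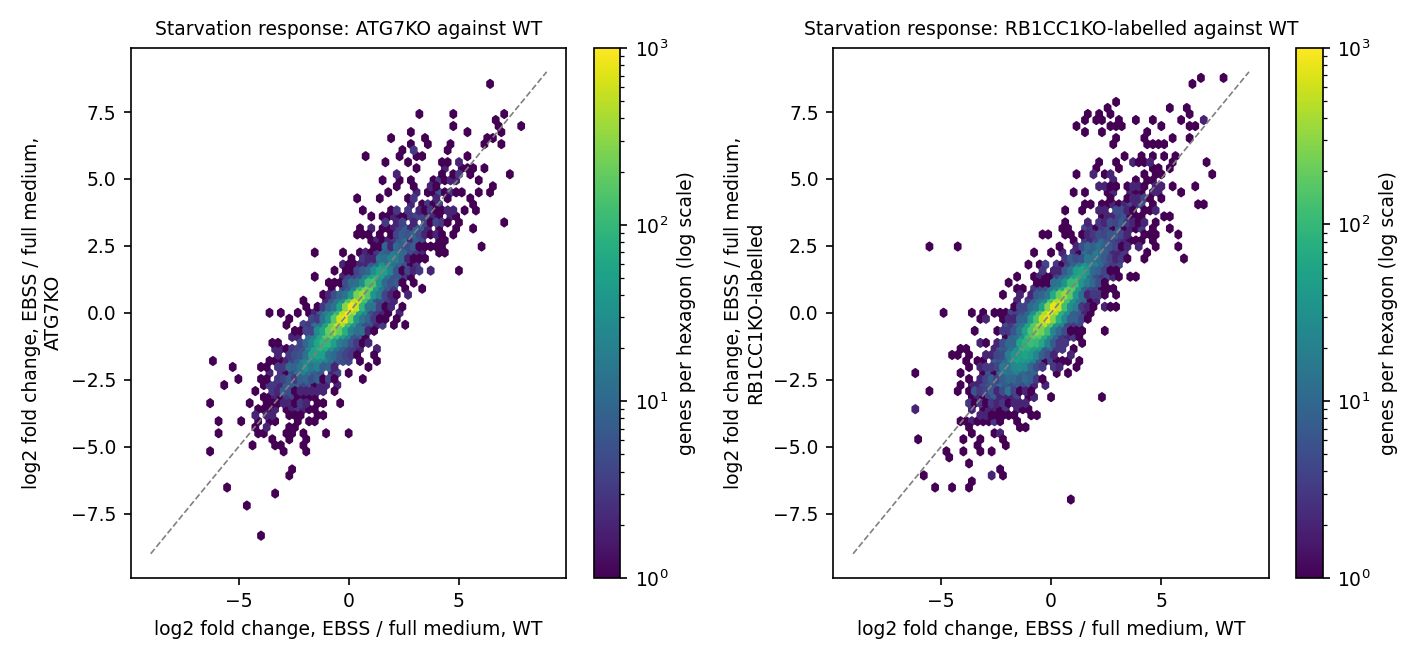
Log2 fold change between EBSS and full medium of 15179 genes in WT (horizontal) against ATG7KO (left) and the RB1CC1KO-labelled line (right), as hexagons coloured by the number of genes on a log scale, with the line of equal change dashed. The correlations across genes are 0.904 and 0.880.

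ATG7KO and WT were then compared in full medium, which asks what differs before starvation. Each genotype is 1 cell line, so effects of a knockout cannot be told apart from other differences between the lines. This holds for every comparison between lines, the differences of the EBSS response included. The p-values rest on the spread between libraries of a line, not between lines of a genotype. RTL8B, a gene of a family with near-identical copies, was 7.24 ± 0.21 log2 units higher in ATG7KO, the secreted factor gene TAFA5 4.97 ± 0.19, EHD3 4.02 ± 0.28 (4.61 without WT replicate 2), TCEAL9 3.79 ± 0.15, the Rac activator TIAM1 3.23 ± 0.31, TMEM132E 3.08 ± 0.18, ELAPOR2 2.93 ± 0.15 and ZNF329 2.87 ± 0.20. FBXO17 had 488 reads in WT and 0 in ATG7KO and was at least 183-fold lower. COL11A1, a fibrillar collagen, was lower by -8.12 ± 0.17, the adhesion molecule CHL1 by -6.94 ± 0.25 (-7.70 without ATG7KO replicate 1), GALNT5 by -6.70 ± 0.19 and the mitotic checkpoint ligase CHFR by -5.77 ± 0.33. Few reads remained of S100A6 (ratio of WT to ATG7KO 160.2, interval 54.4 to 779.8), PCDHB5 (152, 41.6 to 1259) and MFAP2 (111, 30.4 to 924). Of 15179 genes 1599 were called, 678 higher and 921 lower, with 407 at least 2-fold.

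Of the 3 lists of lineage markers 2 differed in ATG7KO. Of 22 haematopoietic markers 8 were measured, and 4 of these were lower and 0 higher (adjusted p = 7.69e-09, 0.00143 with an estimated correlation): the transcription factors TAL1 (-1.91 ± 0.10) and RUNX1 (-0.71 ± 0.12), the receptor KIT (-2.44 ± 0.17) and CD44 (-1.30 ± 0.24). Of 8 epithelial markers 4 were lower and 0 higher (adjusted p = 1.68e-06, 0.0104 with an estimated correlation), namely KRT8 (-1.80 ± 0.12), EPCAM (-4.31 ± 0.48), ESRP1 (-0.69 ± 0.12) and KRT18 (-0.38 ± 0.07). Of 11 fibroblast and mesenchymal markers 3 were higher and 2 lower, and the list did not pass (adjusted p = 0.56, median 0.06, mean -0.16, with the test pointing up). Of 18 targets of YAP and SRF 9 were higher and 1 lower (adjusted p = 0.00382, but adjusted p = 0.134 with an estimated correlation), among them CCN1 (0.61 ± 0.06) and CCN2 (0.64 ± 0.11). These counts were the same when adjusted over the list alone. Of 50 cytosolic ribosomal proteins 6 were higher and 0 lower, or 9 and 0 adjusted over the list alone (adjusted p = 9.74e-05, but adjusted p = 0.858 with an estimated correlation). The nuclear-encoded OXPHOS subunits had 6 of 40 higher and 0 lower, or 10 and 0 (adjusted p = 0.00524, but adjusted p = 0.858 with an estimated correlation). The autophagy machinery had 2 genes higher and 2 lower of 30, also adjusted over the list alone, and did not pass as a list (adjusted p = 0.547). They were ATG13 (-0.27 ± 0.06), BECN1 (-0.23 ± 0.07), GABARAPL2 (0.28 ± 0.09) and GABARAP (0.77 ± 0.25). BECN1 lost its call without filtering, without WT replicate 2 (adjusted p = 0.207) and without ATG7KO replicate 2 or 3 (0.0634, 0.118). GABARAPL2 lost it without WT replicate 1 or 2 (0.119, 0.104) and ATG7KO replicate 1 or 2 (0.0611, 0.203). GABARAP lost it without WT replicate 1 or 2 (0.2, 0.0728), without ATG7KO replicate 2 (0.246), without filtering, in a fit of the compared groups and with DESeq2. EPCAM was at -5.05 without ATG7KO replicate 2. No chromosome as a whole was shifted by a copy, the largest median of a chromosome being -0.07 on chromosome 19.

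The RB1CC1KO-labelled line and WT were compared in the same way, with the caveat that the RB1CC1 RNA was not lower. TCEAL9 was higher by 3.91 ± 0.15, the GABA receptor subunit GABRA5 by 3.87 ± 0.10, ZNF329 by 3.26 ± 0.20, NALF1 by 3.15 ± 0.23, the retinoic acid synthesis enzyme ALDH1A2 by 2.88 ± 0.11, RASGEF1B by 2.64 ± 0.30, DLK1 by 2.56 ± 0.19 and MYH15 by 2.48 ± 0.34. DDIT4L, TRPC4 and RHOB had 0 reads against 320, 172 and 108 in WT and were at least 117-fold, 63.1-fold and 39.6-fold lower. COL11A1 was lower by -9.60 ± 0.19 (-10.31 without RB1CC1KO replicate 3). The ratio of WT to the RB1CC1KO-labelled line was 684 (interval 189 to 5652) for NT5C3A, 632 (175 to 5225) for the growth factor BMP7, 537 (95.9 to 21248) for FBXO17 and 404 (72.0 to 15990.0) for the Wnt receptor FZD10. Of 15179 genes 2606 were called, 1260 higher and 1346 lower, with 565 at least 2-fold.

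Of the lineage lists 2 of 3 differed here. Of 11 measured fibroblast and mesenchymal markers 4 were lower and 0 higher (adjusted p = 6.74e-08, 0.00114 with an estimated correlation). PDGFRA was lower by -2.85 ± 0.14, SPARC by -1.01 ± 0.07 and COL1A1 by -0.31 ± 0.10, a call lost without WT replicate 1 or 3 (adjusted p = 0.114, 0.12) and without RB1CC1KO replicate 2 or 3 (0.134, 0.0823). THY1 had 3 reads against 220 in WT (ratio 80.7, interval 27.2 to 394). Of 8 epithelial markers 4 were lower and 0 higher (adjusted p = 4.15e-07, 0.00332 with an estimated correlation), with ESRP1 at -6.82 ± 0.25 and EPCAM at -4.11 ± 0.47. Of 8 haematopoietic markers 1 was higher and 2 lower, and the list did not pass (adjusted p = 0.4). Of 18 targets of YAP and SRF 8 were lower and 1 higher, or 11 and 1 adjusted over the list alone (adjusted p = 0.00146, but adjusted p = 0.0672 with an estimated correlation), with ACTA2 at -1.06 ± 0.11 and AXL at -1.30 ± 0.20. Of 25 cholesterol genes 7 were higher and 0 lower (adjusted p = 0.0139, but adjusted p = 0.236 with an estimated correlation), with HMGCS1 at 0.45 ± 0.07. The other counts were the same adjusted over the list alone. Cytosolic ribosomal proteins were higher in 10 of 50 cases and lower in 0, or 11 and 0 adjusted over the list alone (adjusted p = 0.00133, but adjusted p = 0.825 with an estimated correlation), and OXPHOS subunits were higher in 6 of 40 and lower in 0, the same over the list alone (adjusted p = 0.0196, but adjusted p = 0.825 with an estimated correlation). The largest median of a chromosome was 0.08, on chromosome 4. The receptor of endoplasmic reticulum autophagy RETREG1 was the 1 receptor called, at -1.53 ± 0.13.

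The 2 knockout-labelled lines shared part of their differences from WT in full medium. Genes higher in both numbered 189 and genes lower in both 231, while 237 went opposite ways. Independent lists of these sizes would share 56.3, 81.7 and 137. Simulations in which all 18 libraries, those of WT included, were drawn with no difference between lines gave 0 shared calls. With nothing changed hardly any gene is called, so this 0 does not weigh the shared controls. The correlation across genes was 0.331, beside 0.528 for simulated unchanged groups, and the covariance 0.131, beside 0.0356, a difference of 0.0954. With only 3 WT libraries the controls could not be split into 2 sets of at least 2, so part of the excess may come from the shared controls. At 2-fold or more in both lines 35 genes were higher, 91 lower and 46 opposite. After EBSS 348 genes were higher in both, 481 lower in both and 258 opposite, beside 136, 184 and 316 from independent lists. The covariance was then 0.158 against 0.0336 simulated, a difference of 0.125.

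After EBSS, ATG7KO differed from WT most in RTL8B (5.71 ± 0.25), the homeobox gene NKX2-4 (4.77 ± 0.34), TAFA5 (4.06 ± 0.20) and TIAM1 (3.39 ± 0.44, or 4.91 without WT replicate 1), which were higher. COL11A1 stood at 0.23 ± 0.169 CPM against 92.2 ± 3.82 in WT (SD, n = 3), FBXO17 and MFAP2 were at least 148-fold and 26.5-fold lower with 0 reads, and S100A6 had 1 read (ratio 268, interval 47.8 to 10624). Immediate early and ERK feedback genes were lower in 13 of 26 cases and higher in 1, or 13 and 4 adjusted over the list alone (adjusted p = 1.16e-05, but adjusted p = 0.175 with an estimated correlation). SPRY2 (-1.10 ± 0.11), MCL1 (-0.44 ± 0.06), EGR2 (-0.92 ± 0.11) and PHLDA1 (-0.79 ± 0.11) led them. Haematopoietic markers were lower in 3 of 8 cases and higher in 0, or 5 and 2 adjusted over the list alone (adjusted p = 1.37e-06, 0.00292 with an estimated correlation), and epithelial markers lower in 4 of 8 and higher in 0, with the same 2 values of p. Of 20 p53 targets 7 were higher and 1 lower (adjusted p = 0.00893, but adjusted p = 0.478 with an estimated correlation). The G1/S list had 9 of 31 higher and 1 lower, or 11 and 2 adjusted over the list alone (adjusted p = 0.0352, but adjusted p = 0.435 with an estimated correlation), and the epithelial and p53 counts stayed the same. Of 2010 genes called 922 were higher and 1088 lower, with 425 at least 2-fold, and without ATG7KO EBSS replicate 2 the count was 1235.

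After EBSS the RB1CC1KO-labelled line had higher GABRA5 (4.07 ± 0.11), NALF1 (3.32 ± 0.23), ALDH1A2 (3.22 ± 0.10) and TCEAL9 (3.21 ± 0.13) than WT. COL11A1 was lower by -9.62 ± 0.19, FBXO17 and FZD10 were at least 232-fold and 55.9-fold lower with 0 reads, and BMP7 had 3 reads (ratio 639, interval 218 to 3104). Genes of cholesterol synthesis and uptake were higher in 16 of 25 cases and lower in 1 (adjusted p = 1.72e-05, but adjusted p = 0.0548 with an estimated correlation), with SREBF2 at 0.62 ± 0.06 and HMGCS1 at 0.66 ± 0.07. Of 29 genes of glycolysis and hypoxia 16 were higher and 1 lower (adjusted p = 4.12e-05, but adjusted p = 0.076 with an estimated correlation), with the glucose carrier SLC2A1 at 0.78 ± 0.07. Of 31 G1/S genes 16 were higher and 0 lower (adjusted p = 0.000591, but adjusted p = 0.114 with an estimated correlation), with CDC25A at 0.52 ± 0.06 and MCM2 at 0.45 ± 0.06. Of 30 G2/M genes 13 were lower and 1 higher (adjusted p = 0.0237, but adjusted p = 0.582 with an estimated correlation), with CENPA at -0.71 ± 0.07 and CCNB1 at -0.43 ± 0.06. Adjusted over the list alone, the cholesterol list had 17 higher and 1 lower, the glycolysis list 18 and 1, and the others the same counts. Cytosolic ribosomal proteins were higher in 15 of 50 cases (adjusted p = 0.000815, but adjusted p = 0.582 with an estimated correlation) and ribosome biogenesis genes in 15 of 33, with 0 and 1 lower (adjusted p = 0.0119, but adjusted p = 0.192 with an estimated correlation). Immediate early and ERK feedback genes had 11 of 26 higher and 4 lower (adjusted p = 0.000986, but adjusted p = 0.192 with an estimated correlation), and YAP and SRF targets 8 of 18 lower and 0 higher (adjusted p = 0.0242, but adjusted p = 0.192 with an estimated correlation). Epithelial markers were lower in 3 of 8 cases and higher in 0 (adjusted p = 0.000815, but adjusted p = 0.076 with an estimated correlation), and fibroblast and mesenchymal markers lower in 5 of 11 and higher in 2 (adjusted p = 0.00284, but adjusted p = 0.0548 with an estimated correlation). Over the list alone ribosome biogenesis had 17 higher and 2 lower, and the other 5 lists kept their counts. Of 4803 genes called 2240 were higher and 2563 lower, with 867 at least 2-fold.

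The 2 knockout-labelled lines were also set against each other in full medium. MFAP2, S100A6 and PCDHB5, which had 2 or 3 reads in ATG7KO, were higher in the RB1CC1KO-labelled line (ratios 345, 145 and 133, intervals 95.1 to 2855, 49.4 to 707 and 36.4 to 1102), as was GALNT5 (6.55 ± 0.19). TRPC4 and DDIT4L were at least 149.9-fold and 112-fold lower, and TAFA5 and NT5C3A had 1 and 2 reads (ratios of ATG7KO to the RB1CC1KO-labelled line 1457 and 730.0, intervals 261 to 57591 and 202 to 6034). Of 18 targets of YAP and SRF 10 were lower in the RB1CC1KO-labelled line and 0 higher, or 12 and 0 adjusted over the list alone (adjusted p = 9.09e-08, 0.0048 with an estimated correlation). AXL differed by -2.11 ± 0.19, ACTA2 by -1.46 ± 0.11, CCN2 by -1.18 ± 0.11 and CCN1 by -0.75 ± 0.06. Fibroblast markers were lower in 4 of 11 cases and higher in 1, also adjusted over the list alone (adjusted p = 7.24e-08, 0.00116 with an estimated correlation), with PDGFRA at -3.48 ± 0.13 and SPARC at -1.59 ± 0.07. Haematopoietic markers went both ways, with 3 of 8 higher and 2 lower, also adjusted over the list alone (adjusted p = 0.00412, but adjusted p = 0.054 with an estimated correlation). TAL1 (2.37 ± 0.09), KIT (2.27 ± 0.17) and RUNX1 (0.60 ± 0.12) were higher, and CD44 (-1.11 ± 0.30) and GATA2 (-0.29 ± 0.08) lower. Cholesterol genes were higher in 14 of 25 cases and lower in 0, or 16 and 1 adjusted over the list alone (adjusted p = 0.0079, but adjusted p = 0.172 with an estimated correlation). The p53 targets had 9 of 20 lower and 2 higher, or 12 and 2 (adjusted p = 0.0244, but adjusted p = 0.489 with an estimated correlation), and the immediate early and ERK feedback genes 10 of 26 lower and 3 higher, the same over the list alone (adjusted p = 0.0486, but adjusted p = 0.489 with an estimated correlation). In all 3249 genes were called, 1732 higher and 1517 lower, and upper-quartile scaling put the higher share at 43.1% in place of 53.3%.

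Whether the response to EBSS differs between ATG7KO and WT was tested as the difference of the 2 responses. Of 26 immediate early and ERK feedback genes 10 had a negative difference and 1 a positive one (adjusted p = 3.81e-12, 0.04 with an estimated correlation). Adjusted over the list alone the counts were 13 and 3. SPRY4, an inhibitor of receptor tyrosine kinase signalling, rose by 4.93 ± 0.29 in WT and 1.65 ± 0.22 in ATG7KO, a difference of -3.28 ± 0.41 (adjusted p = 4.36e-06). DUSP6, an ERK phosphatase, rose in WT and had a value of 0.12 ± 0.26 in ATG7KO (difference -2.28 ± 0.37, adjusted p = 0.000446). PHLDA1 differed by -1.47 ± 0.15 and EGR1 by -0.94 ± 0.15. Outside that list, the cyclooxygenase gene PTGS2 differed by -2.22 ± 0.45 and tissue factor, F3, by -1.94 ± 0.18. In full medium SPRY4 was already higher in ATG7KO than in WT (2.65 ± 0.37), and so was PHLDA1 (0.68 ± 0.11). Of 18 YAP and SRF targets 4 were lower and 0 higher, or 6 and 2 adjusted over the list alone (adjusted p = 0.000215, but adjusted p = 0.0527 with an estimated correlation), with CCN1 at -1.07 ± 0.09 and CCN2 at -1.39 ± 0.18. Of 31 G1/S genes 1 was higher and 0 lower, or 7 and 0 adjusted over the list alone (adjusted p = 0.034, but adjusted p = 0.572 with an estimated correlation). The cytosolic ribosomal proteins passed as a list towards lower values with 0 of 50 genes called either way (adjusted p = 0.0201, but adjusted p = 0.72 with an estimated correlation).

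The differences towards a higher value in ATG7KO were 2.17 ± 0.51 for ADORA1, 2.02 ± 0.51 for NKX2-4, 1.38 ± 0.36 for PLXNB3 and 1.33 ± 0.17 for ATG7 (adjusted p = 0.0231, 0.041, 0.0489 and 6.07e-06). The call of ADORA1 was lost without WT full medium replicate 1 (adjusted p = 0.0504), WT EBSS replicate 2 (0.123), ATG7KO full medium replicate 1 (0.0502) or ATG7KO EBSS replicate 3 (0.0696). That of NKX2-4 was lost without WT full medium replicate 2 or 3 (0.0891, 0.109), WT EBSS replicate 1 or 2 (0.13, 0.143), ATG7KO full medium replicate 1 or 2 (0.0911, 0.0693) or ATG7KO EBSS replicate 2 or 3 (0.129, 0.0642). That of PLXNB3 was lost without any of 10 libraries, all but WT EBSS replicate 3 and ATG7KO EBSS replicate 1 (adjusted p up to 0.25), with upper-quartile scaling (0.0518) and with the stricter filter (0.052). PTGS2 lost its call without ATG7KO full medium replicate 2 (-2.09, adjusted p = 0.0584) and was at -2.83 without ATG7KO EBSS replicate 1. Outside ATG7, which is not in the list of the autophagy machinery, 0 of the 30 genes of that list were called by edgeR and 0 by DESeq2, with 7 at an unadjusted p under 0.05. In the lysosomal list 0 of 43 were called by either tool, with 5 at an unadjusted p under 0.05. In all 160 genes were called, 56 higher and 104 lower, with 23 at least 2-fold. The count was 71 without ATG7KO EBSS replicate 2 and 275 without WT EBSS replicate 3, and single libraries therefore set how many genes are called.

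**Figure D4:**
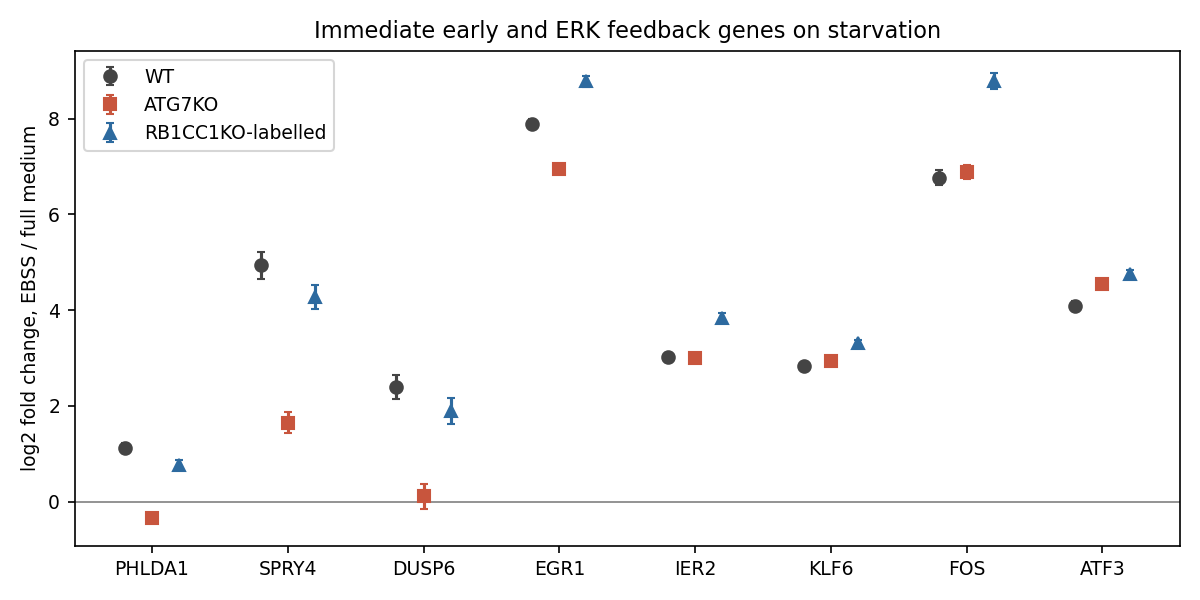
Log2 fold change between EBSS and full medium for immediate early and ERK feedback genes in WT, ATG7KO and RB1CC1KO-labelled cells. Bars show the standard error derived from the F statistic (n = 3 libraries per group). SPRY4 rises by 4.93 in WT and 1.65 in ATG7KO, and FOS rises by 6.77 in WT and 8.78 in the RB1CC1KO-labelled line.

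In the RB1CC1KO-labelled line the response of several immediate early genes was larger than in WT. FOSB differed by 2.62 ± 0.51 (1.91 without WT full medium replicate 3), FOS by 2.02 ± 0.33 (adjusted p = 0.000405), IER2 by 0.83 ± 0.13, ATF3 by 0.65 ± 0.12 and KLF6 by 0.49 ± 0.08. Of 26 genes of that list 8 had a positive difference and 0 a negative one, also adjusted over the list alone. The list passed at adjusted p = 6.06e-07, but adjusted p = 0.115 with an estimated correlation. In full medium FOS had 88 reads in WT (1.98 ± 0.876 CPM). There the list had 1 gene called higher and 1 lower in the RB1CC1KO-labelled line than in WT. At an unadjusted p under 0.05 in edgeR's test, 1 was higher and 6 lower. How far the starting level enters the differences was not tested. LSMEM1 (2.04 ± 0.59) and HCLS1 (1.95 ± 0.30) were the other genes with the largest positive differences. LSMEM1 lost its call without WT full medium replicate 1 or 3 (adjusted p = 0.0898, 0.111) or RB1CC1KO full medium replicate 1 (0.0726). RB1CC1 itself rose less (-0.33 ± 0.10, adjusted p = 0.0305), a call lost in a fit of the compared groups (adjusted p = 0.0741) and without any of 7 libraries (adjusted p up to 0.19): WT full medium 1, WT EBSS 1 and 2, RB1CC1KO full medium 2 and 3, and RB1CC1KO EBSS 1 and 3. The largest negative ones were in MYH15 (-2.15 ± 0.38), RAB42 (-1.96 ± 0.44), PARS2 (-1.92 ± 0.28) and MED7 (-1.73 ± 0.34), where MYH15 rose less and the others fell further than in WT. Of 29 glycolysis and hypoxia genes 8 had a positive difference and 0 a negative one, or 10 and 0 over the list alone. The list passed at adjusted p = 2.6e-06, but adjusted p = 0.115 with an estimated correlation. SLC2A1 was at 0.50 ± 0.10 and VEGFA at 0.46 ± 0.09. On EBSS in WT this list had 11 genes higher and 9 lower, so the sign does not give the size of a response. Of 30 G2/M genes 5 were lower and 0 higher, the same over the list alone (adjusted p = 0.000323, but adjusted p = 0.294 with an estimated correlation), and of 31 G1/S genes 7 were higher and 0 lower, or 9 and 0 (adjusted p = 0.00111, but adjusted p = 0.186 with an estimated correlation). Cholesterol genes were higher in 2 of 25 cases and lower in 0, or 3 and 1 adjusted over the list alone (adjusted p = 0.00233, but adjusted p = 0.162 with an estimated correlation). Ribosome biogenesis had 3 of 33 higher and 0 lower, or 3 and 1 (adjusted p = 0.0393, but adjusted p = 0.294 with an estimated correlation). The ATF4 list had 6 of 31 higher and 1 lower, or 7 and 3 (adjusted p = 0.0393, but adjusted p = 0.349 with an estimated correlation), with a median of -0.03 and a mean of 0.07. Of 43 lysosomal genes 5 had a negative difference and 0 a positive one, or 7 and 0 adjusted over the list alone. The list passed at adjusted p = 0.0474, but adjusted p = 0.241 with an estimated correlation. Among those with a negative difference were ATP6V1C1 (-0.54 ± 0.10), RRAGD (-0.44 ± 0.10), TPP1 (-0.40 ± 0.11) and NEU1 (-0.37 ± 0.10). The calls of TPP1 and NEU1 were lost without any of 4 and 3 libraries (adjusted p up to 0.112 and 0.0987). Of 14 autophagy receptors 2 were lower and 0 higher, and of 30 genes of the machinery 1 was higher and 0 lower (0 and 0 adjusted over the list alone), and neither list passed (adjusted p = 0.423 and 0.821). In all 1238 genes were called, 407 higher and 831 lower, with 161 at least 2-fold. The count was 788 without WT EBSS replicate 1 and 824 without RB1CC1KO full medium replicate 2.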

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

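The results here stand apart because the response to EBSS differed between a knockout-labelled line and WT in a test of the difference itself. The tests of WT cells mixed into the ATG7KO libraries and of induction by EBSS in every line were chosen only after the result was seen.

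In ATG7KO 160 genes had a response that differed from WT. The log2 differences were 1.33 for ATG7, 2.17 for ADORA1, 2.02 for NKX2-4 and 1.38 for PLXNB3, and -3.28 for SPRY4, -2.28 for DUSP6, -2.22 for PTGS2 and -1.94 for F3. Of 100 splits of the 12 libraries, drawn from 200 possible ones, 7 gave as many genes, the real one among them. The highest other split called 646 genes. These splits exchange libraries between WT and ATG7KO, so the difference between the lines enters them and they are no clean null. They cannot decide whether chance gave this count, and chance is not excluded.

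In the RB1CC1KO-labelled line 1238 genes had a response that differed from WT. Of 100 splits 4 gave as many, the real one among them, and the highest other split called 2211 genes. These splits exchange libraries between the lines too, so the difference between the lines enters them. A share under 0.05 is therefore not taken here as excluding chance. The log2 differences were 2.62 for FOSB, 2.04 for LSMEM1, 2.02 for FOS and 1.95 for HCLS1, and -2.15 for MYH15, -1.96 for RAB42, -1.92 for PARS2 and -1.73 for MED7. For RB1CC1 it was -0.33.

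The rise of ATG7 RNA in ATG7KO after EBSS was weighed further. It does not rest on the shallow ATG7KO library, since the difference was 1.34 without it, nor on induction in every line, since the change in WT was 0.05. WT cells mixed in are argued against by 30 genes at least 32-fold lower in ATG7KO, which stood at a median of 0.817% of the WT level after EBSS while ATG7 stood at 64.4%. A candidate explanation is less nonsense-mediated decay of a mutant transcript during starvation, as 20 decay-sensitive genes, none of them in the lists, had a median log2 change of 0.69 (bootstrap SD 0.166) in ATG7KO. The same genes also had a median of 0.69 in WT, and the edited allele is not given in the sources used here, so this stays a hypothesis.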

How the results depend on the processing

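The percent of reads in no gene as a covariate, and leaving out the shallowest library where a comparison does not contain it, were chosen after the data were seen.

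The difference of responses between ATG7KO and WT depended most on the setting. Its 160 genes became 281 without a filter, 293 with the replicate number as a block and 268 with the covariate. The cause was not tested. Leaving out 1 library gave 71 to 275 genes, and 16 to 35 at 2-fold or more, beside 23 with all libraries. The same omissions gave 788 to 1588 genes for the difference between the RB1CC1KO-labelled line and WT, beside 1238, and 1235 to 1922 for ATG7KO against WT after EBSS, beside 2010.

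With a correlation estimated from the data 34 of the 82 list calls passed, and 83 passed with the replicate block and 83 without the shallowest library. Genes shared at 2-fold or more numbered 2282 for EBSS in WT and ATG7KO, 2352 for WT and the RB1CC1KO-labelled line, 126 for the 2 knockout-labelled lines against WT in full medium and 125 after EBSS, beside 8019, 8063, 420 and 829 at any size. The higher bar by its construction passes fewer.

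Of the counts under settings chosen beforehand 270 stayed within 1.5 times and 20 did not, and of those under settings chosen later 34 did and 1 did not. No named gene called in the main fit turned its direction under the alternatives run. Values not called were not checked for this. Replicate numbers did not pair libraries by the rule set beforehand, a correlation of deviations over 0.1 in every pair: over 45 pairs of the same number it ran from -0.132 to 0.221, with a median of 0.007 beside -0.016 for other pairs. Of 18 libraries 0 correlated best with their own number in each of the other groups, while 8 had their single highest correlation with a library of their number. The block was therefore kept as an alternative. Where an omission leaves 2 libraries in a group, the spread is pooled over all groups. At the depths here 1.5-fold changes of the difference of responses were recovered in 47.8% of simulated genes.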

Other observations

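In this part the tests of genomic DNA and of length and expression as the whole cause of the fall in 1-exon genes were chosen only after the result was seen, and so were the genes named in the next paragraph.

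Genes with far lower RNA in both knockout-labelled lines than in WT included the small GTPase gene RHOD, the membrane-fission gene CHMP4C, the cytokine receptor gene LTBR and the cadherin gene CDH13. ARHGAP36 was lower by -3.99 in ATG7KO and -4.08 in the RB1CC1KO-labelled line, and by -3.60 and -3.62 after EBSS. CHFR was lower by -5.77 in ATG7KO and -4.07 in the RB1CC1KO-labelled line. RHOD, CHMP4C and CDH13 were listed at 0 reads in all 12 libraries of these lines.

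The counts of the 8 comparisons of 2 groups were set beside all 10 splits of their 6 libraries, of which 1 gave as many genes, the real one, in each case. The highest other split gave 0 genes in each. Every other split mixes the 2 groups, so their differences count as spread, and 0 is no reference for the real counts. The real counts were 9788, 9554 and 9886 for EBSS in WT, ATG7KO and the RB1CC1KO-labelled line, 1599 and 2606 for these lines against WT in full medium, 2010 and 4803 after EBSS, and 3249 between them. The splits are too few for a share under 0.05.

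The 126 genes changed at least 2-fold the same way in both knockout-labelled lines, 35 higher and 91 lower, were weighed. The shared WT libraries in full medium are argued against as the source, as 77.8% of these genes were called the same way in both lines after EBSS, with other libraries. The comparisons after EBSS share 3 WT libraries of their own, so they are not independent of each other. Gained or lost whole chromosomes are argued against by the chromosome medians, of at most 0.0742 in size in ATG7KO and 0.0805 in the RB1CC1KO-labelled line in full medium. No chromosome thus passed 0.2 log2 units, so the share of these genes on such chromosomes, 0%, would hold for any genes. At most 13 lay on any of 22 chromosomes. Changes of parts of chromosomes were not tested. Drift of the parental WT line and a shared effect of the knockouts stay open and were not tested, since there is 1 parental line and RB1CC1 RNA was not lower in the RB1CC1KO-labelled one.

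Genes with 1 exon fell after EBSS in WT, where the 327 such genes had a median log2 change of -0.47, with 65 higher and 169 lower, and their difference from genes with more exons matched on length and expression was -0.39 (bootstrap SD 0.12), with -0.55 (0.0864) in ATG7KO and -0.79 (0.0951) in the RB1CC1KO-labelled line. This argues against length and expression as the whole cause, while a contribution in WT stays open, as the spread reaches the bound of -0.3 set beforehand. Their deviations followed the percent of reads in no gene across 18 libraries (r = 0.577, permutation p = 0.0197), so genomic DNA may contribute. With that percent as a covariate the matched difference was -0.39 in WT (bootstrap SD 0.12, over genes and not libraries). It was -0.53 in ATG7KO and -0.80 in the RB1CC1KO-labelled line. In WT the percent was 12.2 ± 1.62 in full medium and 11.7 ± 2.20 after EBSS (SD, n = 3), so the covariate could hardly move the value. The percent is also no direct measure of genomic DNA, so this cannot decide whether genomic DNA is the whole cause. No biological explanation was tested.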
